A study of Mus musculus with 29 samples.

How the data were processed

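RNA was extracted from frozen liver or adenoma tissue with silica columns and DNase treatment, and libraries were made with a stranded total RNA kit, per the labels' protocols. The 29 libraries fall into 5 groups by age, label of exposure and tissue. The sample titles give each library a number, which served as its replicate number. For 1 TBT library of 10 months the title and the column name gave different numbers, and the column's number, 9, was used. The labels do not state that each library came from a separate animal, so p values measure the spread between these samples.

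The deposited values are whole-number read counts per coding gene, not normalised. Per the submitters' processing notes, FastQC, Trim Galore, HISAT2, featureCounts and edgeR were used with the mouse build mm10. The order and settings of these steps, their versions, the annotation release and the strand setting are not given in the sources used here. Values of overlapping or antisense genes and of gene families with near-identical members are therefore uncertain, since the counting could split or share their reads. The table held 22028 genes, and 27 symbols stored as dates were restored from their gene identifiers. Coordinates are 1-based on GRCm38 (mm10) and come from GENCODE release M21, matched by gene identifier.

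Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and quasi-likelihood fits with robust dispersion were tested on both sides, with Benjamini-Hochberg adjustment at a threshold of 0.05. The 4 liver groups formed 1 fit of 22 libraries and 13055 genes, which gave the comparisons of TBT and VEH liver at each age, of the ages within each arm, and of their interaction. The 3 groups of 10 months formed another fit of 18 libraries and 13474 genes, which gave the comparisons of adenoma with VEH and with TBT liver. Group levels are given as mean CPM (counts scaled to a common library total) with SD, scaled within the fit. Levels of single libraries are CPM scaled over all 29 libraries without a filter, so they differ slightly from the group values. Fold changes are edgeR's, with SE on the log2 scale.

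Before the data were examined, 40 gene lists were fixed from textbook knowledge of liver, its cell types and the exposure. Of their 869 entries, 13 matched no gene in the table, and 38 lists had at least 5 tested genes. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 between genes. Calls were repeated with the correlation estimated from the data and with fry, which tests a list without comparing it to other genes. Named genes followed a rule set before the data were examined. In each comparison the rule took the 10 largest changes in each direction among called genes with a mean of at least 2 CPM in a group, without predicted genes, and up to 4 members of each called list by smallest adjusted p. The 5 genes with the smallest p were taken where fewer than 5 genes passed. Pparg, Cidea, Cidec, Fasn, Scd1, Afp, Glul, Cyp7a1 and Mki67 were always included. Other genes named singly to illustrate a list, such as Marco, Clec4f, E2f8, Fabp5 and Por, were chosen after their values were seen.

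Alternatives set before the data were examined were median-of-ratios scaling, no filter and a stricter filter (at least 1 CPM in at least 5 libraries), DESeq2 1.42.0, limma-voom, other sets of groups in the fit, the replicate number as a block, and omission of each library in turn. Omission of the 5-month libraries with unusual values and thinning of counts to the smallest library total were added after the data were seen. Correlations of fold changes across genes were set against 100 relabellings of the samples or 20 simulations of unchanged groups with shared controls. Counts of called genes were set against 100 splits of the same samples. The tests were checked on simulated counts with known changes drawn from the real means and depths. For TBT against VEH liver at 5 months, edgeR recovered 20.9% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 100% of those changed 4-fold. For adenoma against VEH liver the shares were 50.7%, 86.6% and 97%. The simulated groups were uniform and held no libraries with unusual values. The shares therefore do not measure recovery or false calls among the real 5-month libraries. Replicate pairs were compared for duplicated libraries, and 0 pairs were identical, with a chi-square per degree of freedom of at least 18.3 in every pair.

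The TBT libraries of 5 months were shallower on average than those of the other groups (7513448 to 19270524 counts), which widens the error of low genes in that group. The deepest of them passed the shallowest VEH library of 5 months (18603160 counts). Fold changes of genes with 0 counts in a whole group depend on the prior count, so only levels are given for them. Results for some genes named by the rule are not reported here.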

Results

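RNA from mouse liver was sequenced to ask whether exposure to tributyltin (TBT) early in life left differences in adult liver. TBT is an organotin compound known to activate the nuclear receptors PPARG and RXR. Mothers took TBT through their drinking water while pregnant and nursing, and the male offspring were sampled at 5 and 10 months of age. The comparison arm carries the label VEH and was read here as the control arm. At 5 months there were 6 VEH and 5 TBT liver libraries, and at 10 months there were 6 VEH and 5 TBT liver libraries and 7 libraries of adenoma, a benign liver tumour. All adenomas carry the TBT label, so tumour and exposure cannot be separated in comparisons against VEH liver. The numbers of the TBT livers and adenomas of 10 months do not overlap. These livers may thus come only from animals without an adenoma library, which the labels do not state. Total counts per library were 18603160 to 33704303 for VEH and 7513448 to 19270524 for TBT at 5 months. At 10 months they were 25714194 to 30362835 for VEH, 25973945 to 32850438 for TBT and 21920649 to 27563960 for the adenomas.

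The libraries of 5 months were not uniform. VEH replicates 4 and 6 and TBT replicate 4 carried 72.9, 123 and 95.0 CPM of Ly6d, a surface protein gene on the list of liver tumour genes, while the other 8 libraries of that age carried at most 8.09 CPM. In the same 3 libraries Hsd3b5, a steroid-metabolising enzyme of male mouse liver, was at 1.44, 0.462 and 0.544 CPM, against 134 to 336 CPM in the other 8. TBT replicate 2 carried 668 CPM of Sis and 401 CPM of Alpi, which encode enzymes of the intestinal brush border. Because these libraries lie in both arms, counts for comparisons that use 5-month liver are also given without them, a choice made after the data were seen.

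At 5 months, genes of the circadian clock differed between TBT and VEH liver. Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), was at 5.00 ± 2.79 CPM in TBT liver and 24.5 ± 10.1 CPM in VEH liver (SD, n = 5 and 6). Its log2 fold change was -2.28 (SE 0.41, adjusted p = 0.0148), and all 5 TBT libraries lay below every VEH library. Per3, a member of the period family of clock repressors (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), was higher, at 11.1 ± 4.68 against 1.51 ± 1.22 CPM (log2 fold change 2.86, SE 0.55, adjusted p = 0.015, above all VEH libraries in 5 of 5). The transcription factor Tef, an output of the clock, was at 146 ± 39.4 against 43.6 ± 20.9 CPM (log2 fold change 1.74, SE 0.33, adjusted p = 0.015, above all VEH libraries in 5 of 5). Nfil3, a repressor that opposes Tef and Dbp at their shared targets, was lower (log2 fold change -1.26, SE 0.27, adjusted p = 0.0215, below the VEH mean in 5 of 5 and below all VEH libraries in 4). Of the 19 clock genes measured, 6 were higher and 2 lower at the threshold over all genes tested, and 8 were higher and 4 lower when adjusted over the list alone. The other genes called were Usp2 (log2 fold change 2.47), Dbp (3.55), Per2 (1.43) and Nr1d2 (1.02), the last 3 named after their values were seen. The list's median log2 fold change was 0.63 (camera adjusted p = 0.00195), and adjusted p = 0.369 with an estimated correlation. Without VEH replicates 4 and 6 and TBT replicates 2 and 4, edgeR called 0 clock genes, with a smallest adjusted p of 0.0661. Of the 19 clock genes, 12 had an unadjusted p under 0.05 there, among them all 8. The 8 were chosen in a fit that included the remaining libraries, so this is not separate support. The median size of the log2 fold changes of these 8 was 1.95 against 2.01 with all libraries. Arntl, Per3, Tef and Usp2 were called in all 11 fits that left out a library, and Nfil3 in all but that without TBT replicate 2 (adjusted p = 0.0678).

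Some genes of the acute phase response, the liver's secretory response to inflammation, were lower in TBT liver at 5 months. Hamp, which encodes the iron-regulating hormone hepcidin (ENSMUSG00000050440, chromosome 7, 30942368 to 30944032), was at 109 ± 71.0 CPM against 434 ± 158 CPM in VEH liver (log2 fold change -2.00, SE 0.43, adjusted p = 0.0214, below the VEH mean in 5 of 5). The fibrinogen chain genes Fga, Fgb and Fgg had log2 fold changes of -1.05, -1.08 and -1.02 (adjusted p = 0.0235, 0.0357 and 0.0299, each below the VEH mean in 5 of 5). The metalloreductase gene Steap4 had -1.58 (adjusted p = 0.0379, below the VEH mean in 5 of 5). These 5 of 29 members were lower and 0 higher, both over all genes tested and adjusted over the list alone (list median -0.85, camera adjusted p = 3.86e-11, adjusted p = 0.772 with an estimated correlation). The list had a fry adjusted p of 0.0985, and a camera adjusted p of 0.00834 without VEH replicates 4 and 6 and TBT replicates 2 and 4. The acute phase gene Saa2 varied within both arms, from 121 to 14800 CPM in VEH and from 15.6 to 8160 CPM in TBT libraries. Atf4, a transcription factor of the integrated stress response, fell by 0.50 on the log2 scale (SE 0.09, adjusted p = 0.015, below all VEH libraries in 5 of 5). It was the only member of 24 on the stress response list to pass (list median -0.23, camera adjusted p = 0.0347, adjusted p = 0.994 with an estimated correlation). Cdkn1a, the p53-induced inhibitor of the cell cycle, was lower (log2 fold change -2.22, adjusted p = 0.0448, below the VEH mean in 5 of 5 and below all VEH libraries in 3). Afp, alpha-fetoprotein of fetal liver, was higher (1.57, adjusted p = 0.0438, above all VEH libraries in 4 of 5). The 10 genes with the largest increases included brush border and intestinal genes, led by Fcgbp (log2 fold change 8.45, SE 1.68, adjusted p = 0.0167), Cdhr2 (5.78) and Slc5a1 (4.94). Fcgbp was at 634 CPM in TBT replicate 2 and at 0.286 to 1.20 CPM in the other 4 TBT libraries. Lars2 (6.86), a mitochondrial leucyl-tRNA synthetase gene, was at 26900 CPM in TBT replicate 4.

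Several of these calls at 5 months rested on single libraries, whereas Atf4 was called in all 11 fits that left out a library. Without TBT replicate 2, Hamp, Fga and Fcgbp were no longer called (adjusted p = 0.0607, 0.0692 and 0.509). Fgg was lost without TBT replicate 2 or VEH replicate 3 or 5 (highest adjusted p = 0.081). Fgb was called only without TBT replicate 3 or VEH replicate 2 or 4 (highest adjusted p otherwise 0.0984), and Steap4 only without TBT replicate 5 or VEH replicate 1, 2 or 3 (0.0934). Cdkn1a was called only without TBT replicate 4 or 5 or VEH replicate 3 (0.0937), and Afp only without TBT replicate 3, 5 or 6 or VEH replicate 3 (0.134). Cdhr2 and Slc5a1 were lost without TBT replicate 2 or any of VEH replicates 1 to 5 (highest adjusted p = 0.981 and 0.653). Lars2 was lost without TBT replicate 4 or any of VEH replicates 2 to 5 (0.195). The stress response list was lost without TBT replicate 2, 3 or 4 or VEH replicate 5 (0.361).

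Lipid genes tied to PPARG, the receptor TBT is known to activate, did not pass at 5 months. Of 19 lipid droplet and PPARG target genes, edgeR called 0 (list median log2 fold change 0.00, camera adjusted p = 0.965). Pparg itself had a log2 fold change of 0.76 (SE 0.41, adjusted p = 0.388). The lipid droplet genes Cidea and Cidec had 0.65 (SE 1.24) and -0.12 (SE 0.66), while the lipogenic enzymes Fasn and Scd1 had -0.35 (SE 0.57) and 0.13 (SE 0.47).

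In all, edgeR called 265 of 13055 genes at 5 months, 140 higher and 125 lower in TBT liver, 48 and 20 of them by at least 2-fold. Erythroid and nuclear oxidative phosphorylation lists tested as higher, with list medians of 0.83 and 0.12 (camera adjusted p = 0.000882 and 0.00651), and the mitochondrially encoded list as lower, with a median of -0.66 (camera adjusted p = 0.0204). Their adjusted p values were 0.7, 0.994 and 0.994 with an estimated correlation. DESeq2 called 591 genes and limma-voom 147, a fit of these groups alone called 1, and counts thinned to the smallest library gave 153. Omission of VEH replicates 4 and 6 and TBT replicate 4 gave 308, and omission of TBT replicate 2 as well left 47, of which 27 were among the 265. The count also moved to 71, 414 and 410 without TBT replicate 2, 4 or 6 and to 122, 163 and 164 without VEH replicate 1, 2 or 5. The mitochondrially encoded list was no longer called without VEH replicate 1, 2 or 5 or TBT replicate 3 (highest adjusted p = 0.164), nor the oxidative phosphorylation list without TBT replicate 2, 5 or 6 (highest 0.175).

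At 10 months, TBT and VEH liver did not differ in any gene at the threshold. This holds for the TBT livers sequenced, which may be a subset of animals without adenoma libraries. EdgeR called 0 of 13055 genes (218 at an unadjusted p under 0.05), DESeq2 called 0 (284 unadjusted) and limma-voom called 0 (319 unadjusted), and the smallest edgeR adjusted p was 1. The smallest unadjusted p values belonged to Cdc42ep1, an effector of the small GTPase CDC42 (19.9 ± 3.38 against 13.6 ± 1.19 CPM, SD, n = 5 and 6, log2 fold change 0.55, SE 0.13), and Hmga1, a chromatin architectural protein gene (log2 fold change 0.42, SE 0.11). They were followed by Zfyve1 (-0.34), C77080 (0.56) and Arsa (0.56), all with adjusted p = 1. Pparg, Cidea and Cidec had log2 fold changes of 0.22 (SE 0.39), 0.25 (SE 0.85) and 0.81 (SE 0.68). Of the 19 lipid droplet and PPARG target genes 0 passed (list median 0.13, camera adjusted p = 0.977). The spread in this fit was estimated together with the non-uniform 5-month libraries, which may make the test cautious. In the fit of the 3 groups of 10 months, edgeR also called 0 genes, with 595 at an unadjusted p under 0.05. In simulated counts with these means and depths but uniform groups, 79.1% of genes changed 2-fold and 23.9% of genes changed 1.5-fold were recovered.

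Of 38 gene lists, 13 tested at this age under the preset correlation although none of their members passed, over all genes or adjusted over the list alone. The interferon response list had a median log2 fold change of 0.29 in TBT liver (camera adjusted p = 6.32e-11, adjusted p = 0.203 with an estimated correlation). Its members Usp18 and Isg15, an interferon-induced protease gene and its ubiquitin-like partner, had log2 fold changes of 0.58 and 0.58 (SE 0.23 and 0.26, both adjusted p = 1); both members were picked after the values were seen. Male-biased liver genes had a median of -0.42 (camera adjusted p = 0.000333) and mitochondrially encoded genes -0.33 (camera adjusted p = 9.35e-05), while stellate cell and fibrosis genes had 0.19 (camera adjusted p = 0.00207). Each of these had adjusted p = 0.878 with an estimated correlation. The self-contained test fry called 0 lists.

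In adenomas, genes of proliferation and of liver tumours were higher than in VEH liver of 10 months. Ly6d (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620) was at 210 ± 143 CPM in adenomas and 1.15 ± 0.478 CPM in VEH liver (SD, n = 7 and 6; log2 fold change 7.52, SE 0.68, adjusted p = 4.42e-07, above all VEH libraries in 7 of 7). The proliferation marker Mki67 was at 41.4 ± 22.8 against 3.48 ± 2.08 CPM (log2 fold change 3.57, SE 0.49, adjusted p = 1.9e-05, above the VEH mean in 7 of 7). Cdk1, the mitotic kinase, had a log2 fold change of 3.88. Of 32 cell cycle genes 31 were higher and 1, E2f8, was lower (list median 2.92, camera adjusted p = 5.45e-09, adjusted p = 0.396 with an estimated correlation). Of 29 liver tumour and oncofetal genes 27 were higher and 1, Fabp5, was lower (median 3.28, camera adjusted p = 9.17e-12, adjusted p = 0.196 with an estimated correlation). Among them were the transcription factor gene Sox4 (2.84), the collagen receptor gene Ddr1 (3.92) and the stem cell surface marker Prom1 (2.75). Afp rose by 2.04 (SE 0.42, adjusted p = 0.000614, above all VEH libraries in 7 of 7). Adjusted over the list alone, the counts for both lists were the same. Lrtm2, a leucine-rich repeat protein gene (ENSMUSG00000055003, chromosome 6, 119315133 to 119330766), was at 19 ± 6.74 against 0.0421 ± 0.0537 CPM (log2 fold change 8.72, SE 0.61, adjusted p = 2.15e-08, above all VEH libraries in 7 of 7). The cystine transporter gene Slc7a11 reached 45.3 ± 50.7 CPM. Tekt5 and Eps8l3 reached 4.90 ± 5.13 and 3.90 ± 3.33 CPM with 0 counts in every VEH library of that age.

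Markers of bile duct, stroma and immune cells were also higher in adenomas. Of 14 cholangiocyte markers 12 were higher and 0 lower over all genes tested, and 13 higher and 1 lower adjusted over the list alone (median 2.32, camera adjusted p = 1.04e-06, adjusted p = 0.0658 with an estimated correlation). Among them were the secreted phosphoprotein gene Spp1 (log2 fold change 3.27), the adhesion molecule gene Epcam (2.53) and the chloride channel gene Cftr (4.75). Of 30 stellate cell and fibrosis genes 23 were higher and 3 lower (median 1.34, camera adjusted p = 3.44e-08, adjusted p = 0.368 with an estimated correlation). The collagen genes Col6a3 and Col1a2 had log2 fold changes of 2.33 and 2.19. Interferon response genes rose in 26 of 27 cases with 0 lower (median 1.64, camera adjusted p = 2.51e-10, adjusted p = 0.368 with an estimated correlation). They included the antiviral GTPase gene Mx1 (2.59) and the chemokine gene Cxcl10 (2.80). T and NK cell markers were higher for 16 of 18 with 0 lower (median 1.24, camera adjusted p = 2.69e-05, adjusted p = 0.368 with an estimated correlation), for example the CD8 chain gene Cd8a (2.44). All 8 MHC class II genes were higher (median 2.00, camera adjusted p = 3.83e-05, adjusted p = 0.383 with an estimated correlation), although members of this family share reads. Macrophage markers went both ways, with 20 higher and 3 lower of 27 (median 1.04, camera adjusted p = 0.000231, adjusted p = 0.383 with an estimated correlation). Gpnmb, a gene of lipid-associated macrophages, had a log2 fold change of 5.29 (SE 0.45), while the resident Kupffer cell markers Timd4 and Clec4f and the scavenger receptor gene Marco were lower (-4.04, -1.03 and -3.93). Cd163, a scavenger receptor gene of resident macrophages (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), was at 0.875 ± 0.392 against 22.9 ± 5.44 CPM (log2 fold change -4.72, SE 0.29, adjusted p = 6.91e-09, below all VEH libraries in 7 of 7).

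Genes of the detoxifying NRF2 pathway and of p53 were higher in adenomas. Of 23 NRF2 targets 14 were higher and 1, the malic enzyme gene Me1, was lower (median 0.61, mean 2.10, camera adjusted p = 6.44e-05, adjusted p = 0.383 with an estimated correlation). The glutathione transferase gene Gstm3 was at 449 ± 288 against 12.7 ± 4.54 CPM (log2 fold change 5.14, SE 0.56, adjusted p = 2.34e-06, above all VEH libraries in 7 of 7). Gsta1 and Gsta2 also rose, with values that are uncertain because close paralogs share reads. Of 20 p53 targets 12 were higher and 2 lower (median 0.73, camera adjusted p = 0.00306, adjusted p = 0.383 with an estimated correlation), including Cdkn1a (2.50) and Phlda3 (3.12). Of 17 immediate early genes 10 were higher and 0 lower, and 11 and 0 adjusted over the list alone (median 1.15, camera adjusted p = 0.00307, adjusted p = 0.383 with an estimated correlation). The stress-induced factor gene Atf3 was at 2.89.

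Several lists of hepatocyte genes and the male-biased list were lower in adenomas. The lists of xenobiotic metabolism and of urea cycle and amino acid catabolism were not called. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252) was at 5.56 ± 5.58 against 248 ± 53.8 CPM (log2 fold change -5.49, SE 0.66, adjusted p = 5.54e-06, below all VEH libraries in 7 of 7). Of 23 male-biased liver genes 16 were lower and 0 higher, and 17 lower adjusted over the list alone (median -1.65, camera adjusted p = 3.08e-07, adjusted p = 0.368 with an estimated correlation). They included Cyp2d9 (-1.65) and major urinary protein genes such as Mup12 (-6.07), whose family shares reads. Of 22 cholesterol synthesis genes 21 were lower and 0 higher (median -1.01, camera adjusted p = 3.08e-07, adjusted p = 0.383 with an estimated correlation), such as Hsd17b7 (-1.43), Idi1 (-1.44) and Msmo1 (-1.46). Of 20 lipogenesis genes 14 were lower and 0 higher (median -0.96, camera adjusted p = 0.00154, adjusted p = 0.554 with an estimated correlation). The triglyceride-forming enzyme gene Dgat2 (-1.14) and the acetyl-CoA synthetase gene Acss2 (-1.94) were among them. Secreted hepatocyte products were lower for 17 of 24 genes (median -0.56, camera adjusted p = 1.03e-06, adjusted p = 0.37 with an estimated correlation), such as Apoa2 (-0.98) and Ttr (-0.78). Of 22 genes of the pericentral zone or downstream of beta-catenin 9 were lower and 1 higher (median -0.65, camera adjusted p = 0.00165, adjusted p = 0.554 with an estimated correlation). The ethanol-oxidising enzyme gene Cyp2e1 was at -1.74 and the glutamine synthetase gene Glul at -1.06 (adjusted p = 0.0277, below all VEH libraries in 6 of 7). The Glul call was lost without adenoma 1, 3, 5, 11 or 12 or VEH replicate 1 (highest adjusted p = 0.0546). Of 20 bile acid genes 11 were lower and 4 higher, and 12 and 5 adjusted over the list alone (median -0.89, camera adjusted p = 0.0157, adjusted p = 0.383 with an estimated correlation). The bile acid receptor gene Nr1h4 was at -1.10 and the efflux pump gene Abcc4 at 3.58.

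**Figure D1:**
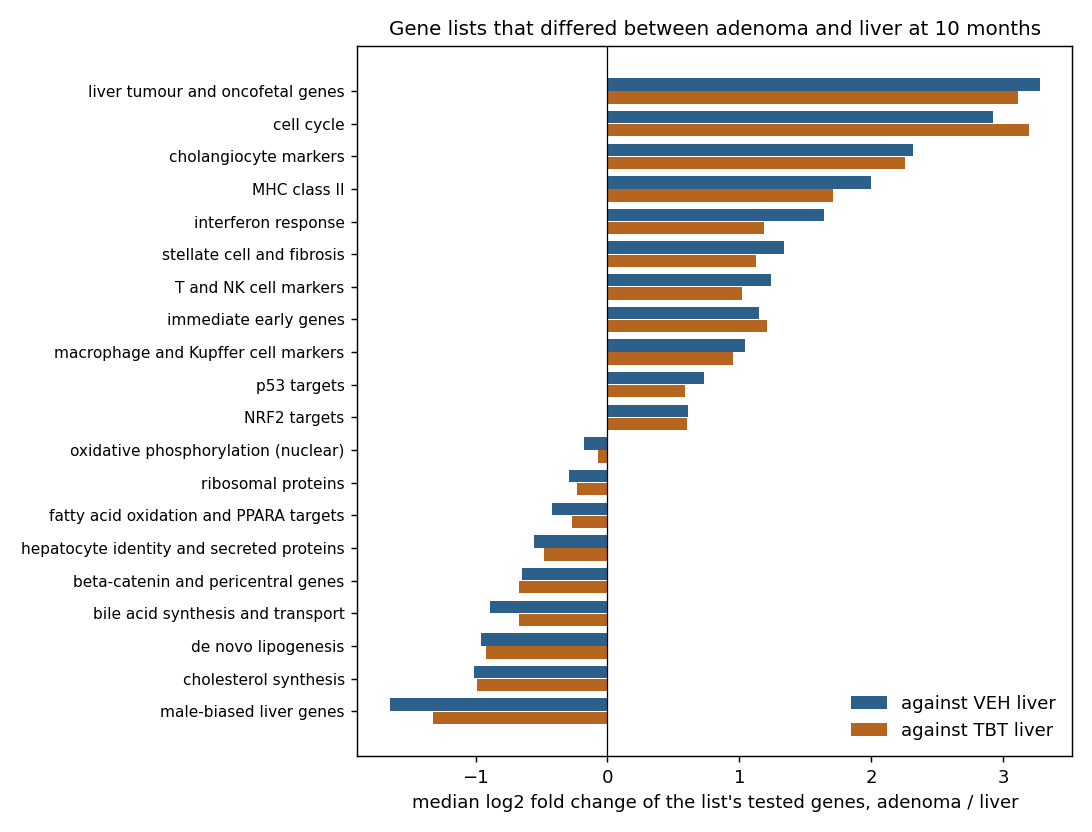
Median log2 fold change of gene lists in adenoma against VEH liver (blue bars) and TBT liver (orange bars) at 10 months, for the 20 lists called in both comparisons. Against VEH liver, 11 of them lie above 0 and 9 below, from 3.28 for liver tumour and oncofetal genes to -1.65 for male-biased genes.

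Against VEH liver, edgeR called 7090 of 13474 genes (52.6%), 3755 higher and 3335 lower in adenomas, with 1956 and 363 of them changed at least 2-fold. DESeq2 called 7259 and limma-voom 7070 genes, and counts without each library in turn were 6571 to 7365. Of the 38 lists tested, 22 were called under the preset correlation and 0 with an estimated correlation, while fry's adjusted p was under 0.05 for all 22.

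Against TBT liver of the same age, the same kinds of genes parted adenoma from liver. Ly6d was at 210 ± 143 against 2.20 ± 1.29 CPM (SD, n = 7 and 5; log2 fold change 6.59, SE 0.69, adjusted p = 4.28e-06, above all TBT livers in 7 of 7). Mki67 was at 41.4 ± 22.8 against 3.79 ± 1.31 CPM (3.45, SE 0.52, adjusted p = 8.21e-05, above all TBT livers in 7 of 7). Cholangiocyte markers rose for 13 of 14 genes with 1 lower (median 2.26, camera adjusted p = 2.07e-07), the only list called with both correlations (adjusted p = 0.0394 with an estimated correlation). Cell cycle genes were higher for 31 of 32 (median 3.20, camera adjusted p = 2.63e-10, adjusted p = 0.345 with an estimated correlation). Tumour and oncofetal genes were higher for 27 of 29 (median 3.11, camera adjusted p = 8.73e-13, adjusted p = 0.153 with an estimated correlation). Interferon response genes were higher for 24 of 27 (median 1.19, camera adjusted p = 5.61e-09, adjusted p = 0.338 with an estimated correlation). Cholesterol synthesis genes were lower for 19 of 22, and for 21 adjusted over the list alone (median -0.99, camera adjusted p = 5.19e-08, adjusted p = 0.338 with an estimated correlation). Cd163 (-4.90), Timd4 (-4.18), Hsd3b5 (-5.41) and the organic anion transporter gene Slco1a1 (-3.92) were each below all TBT livers in 7 of 7 adenomas. Of 25 nuclear receptor genes 3 were higher and 11 lower (median -0.17, camera adjusted p = 0.0365, adjusted p = 0.338 with an estimated correlation). The retinoic acid receptor gene Rarg was at 1.11 and the orphan receptor gene Nr2f6 at -0.41. The nuclear receptor call was lost without adenoma 6 or 11 (highest adjusted p = 0.0515). EdgeR called 6026 of 13474 genes, 3223 higher and 2803 lower, with 1708 and 289 changed at least 2-fold. DESeq2 called 6272 and limma-voom 6031.

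With age, interferon and acute phase genes fell in VEH liver. Mt1, a metallothionein gene on the acute phase list (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), was at 10.2 ± 11.0 CPM at 10 months and 682 ± 613 CPM at 5 months (SD, n = 6 and 6; log2 fold change -6.06, SE 1.01, adjusted p = 0.000563, below all 5-month libraries in 6 of 6). The interferon-induced ubiquitin-like gene Isg15 was at 2.21 ± 0.239 against 7.75 ± 2.33 CPM (log2 fold change -1.80, SE 0.26, adjusted p = 0.000134, below all 5-month libraries in 6 of 6). Of 27 interferon response genes 21 were lower and 0 higher, and 22 lower adjusted over the list alone (median -0.91, camera adjusted p = 1.02e-12, adjusted p = 0.117 with an estimated correlation). The nucleic acid sensor gene Zbp1 was at -1.63. Of 29 acute phase genes 21 were lower and 0 higher, and 23 lower adjusted over the list alone (median -1.72, camera adjusted p = 1.26e-11, adjusted p = 0.748 with an estimated correlation). Steap4 was at -2.74, Fgb at -1.47 and the interleukin 1 receptor antagonist gene Il1rn at -2.19. The basement membrane collagen genes Col4a1 and Col4a2, at -1.27 and -1.34, were among the stellate cell and fibrosis genes that fell. Of 30 genes on that list 8 were lower and 0 higher, and 19 lower adjusted over the list alone (median -0.97, camera adjusted p = 3.12e-05, adjusted p = 0.832 with an estimated correlation).

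Some xenobiotic and bile acid genes were higher in older VEH liver. The carboxylesterase gene Ces1d (ENSMUSG00000056973, chromosome 8, 93166068 to 93197838) was at 1440 ± 415 against 307 ± 145 CPM (log2 fold change 2.23, SE 0.38, adjusted p = 0.000548, above all 5-month libraries in 6 of 6). Of 33 xenobiotic metabolism genes 8 were higher and 1, the reductase gene Por, was lower, and 8 and 2 adjusted over the list alone (median 0.29, camera adjusted p = 0.011, adjusted p = 0.748 with an estimated correlation). Of 20 bile acid genes 4 were higher and 0 lower, and 5 higher adjusted over the list alone (median 0.45, camera adjusted p = 0.009, adjusted p = 0.832 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 2.47 (adjusted p = 0.0151, above the 5-month mean in 6 of 6). Pparg and Cidea were higher (log2 fold changes 1.29 and 3.22, adjusted p = 0.0247 and 0.0282, each above the 5-month mean in 6 of 6), while Cidec was lower (-2.57, adjusted p = 0.0124, below the 5-month mean in 6 of 6 and below all 5-month libraries in 2). The Pparg call was lost without VEH replicate 2 of 10 months (adjusted p = 0.0685), and that of Cidea without the same library or VEH replicate 1, 4 or 5 of 5 months (highest 0.0818). EdgeR called 2501 of 13055 genes, 1189 higher and 1312 lower, with 173 and 306 changed at least 2-fold. The tumour-linked genes Ly6d (-5.07) and Gpnmb (-4.76) were among those lower at 10 months. The Gpnmb call was lost without VEH replicate 1, 4 or 6 of 10 months or 6 of 5 months (highest adjusted p = 0.121). Without VEH replicates 4 and 6 and TBT replicate 4 of 5 months Gpnmb turned to 0.95 (adjusted p = 0.226), Ly6d was at -2.33 (adjusted p = 0.00281) and the called lists went from 14 to 7. The count of genes was then 2162, with 1094 higher and 1068 lower. Age and any batch of collection or sequencing cannot be told apart.

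In TBT liver fewer genes passed between the ages, in a comparison with fewer libraries and shallower ones at 5 months. In simulated counts 59.7% of genes changed 2-fold were recovered for TBT liver, against 71.6% for VEH liver. The interaction of age and exposure gave 0 genes in edgeR. Cyp2j9, a cytochrome P450 gene (ENSMUSG00000015224, chromosome 4, 96568429 to 96591578), was at 7.89 ± 2.05 CPM at 10 months and 2.76 ± 0.345 CPM at 5 months (SD, n = 5 and 5; log2 fold change 1.5, SE 0.18, adjusted p = 0.000386, above all 5-month libraries in 5 of 5). Arntl was higher at 10 months (2.17, SE 0.42, adjusted p = 0.0209, above all 5-month libraries in 5 of 5). The collagen gene Col5a3 had a log2 fold change of 1.07 (adjusted p = 0.0158, above all 5-month libraries in 5 of 5). The metallothionein genes Mt1 and Mt2 were lower (-4.42 and -5.09, adjusted p = 0.0405 and 0.0461, 5 of 5 below the 5-month mean), as was Il1rn at -1.5 (adjusted p = 0.0472, below the 5-month mean in 5 of 5). These 3 of 29 acute phase genes were lower, and 3 adjusted over the list alone (median -0.77, camera adjusted p = 0.023, adjusted p = 0.824 with an estimated correlation). The list was no longer called without TBT replicate 4, 9 or 10 of 10 months or 3 or 5 of 5 months (highest adjusted p = 0.94). None of 27 interferon response genes passed over all genes in edgeR, and 7 were lower adjusted over the list alone (median -0.44, camera adjusted p = 3.33e-05, adjusted p = 0.824 with an estimated correlation). Of 8 erythroid genes 6 were lower adjusted over the list alone and 0 over all genes (median -2.07, camera adjusted p = 2.75e-05, adjusted p = 0.508 with an estimated correlation), and the haemoglobin genes among them share reads. The intestinal genes of TBT replicate 2 of 5 months were among the genes lower at 10 months (Cdhr2 -7.89, Fcgbp -7.63). Without that library and the 3 with high Ly6d, Fcgbp turned to 0.20 (adjusted p = 0.848).

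EdgeR called 232 of 13055 genes in TBT liver with age, 94 higher and 138 lower, with 15 and 61 changed at least 2-fold. DESeq2 called 843, limma-voom 35, a fit of all 5 groups 401 and a fit of the groups compared alone 0 (1881 unadjusted). Thinned counts gave 58, and omission of the 4 libraries 113, of which 66 were among the 232. The count was 14, 48, 34, 25 and 24 without TBT replicate 10, 2, 4, 8 or 9 of 10 months and 104 and 801 without TBT replicate 4 or 6 of 5 months. Arntl was lost without TBT replicate 8, 9 or 10 of 10 months (highest adjusted p = 0.0648) and Col5a3 without replicate 10 (0.0526). Mt1, Mt2 and Il1rn were each lost without TBT replicate 2, 4, 8, 9 or 10 of 10 months or 4 of 5 months, and Mt2 and Il1rn also without 3 or 5 of 5 months (highest 0.0992, 0.111 and 0.126). Fcgbp and Cdhr2 were lost without any 1 of the 5 TBT libraries of 10 months or without TBT replicate 2 of 5 months (highest 0.918 and 0.231). Cyp2j9 was called in every one of the 10 fits that left out a library.

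By edgeR, the difference between TBT and VEH liver did not pass a test of change with age in any gene. EdgeR called 0 of 13055 genes for the interaction of age and exposure (1139 at an unadjusted p under 0.05, smallest adjusted p = 0.231), limma-voom called 0 (1152 unadjusted) and DESeq2 called 44 (1297 unadjusted). Without VEH replicates 4 and 6 and TBT replicate 4 of 5 months edgeR called 0 (1595 unadjusted), and without TBT replicate 2 as well 0 (1482 unadjusted). Zfp941, a zinc finger gene, and Tnk2, a tyrosine kinase gene, had the smallest p values (log2 differences 1.93 and 0.92, SE 0.37 and 0.18, both adjusted p = 0.231). Acute phase genes shifted up in TBT relative to VEH between 5 and 10 months by a list median of 0.93 (camera adjusted p = 2.45e-09, adjusted p = 0.725 with an estimated correlation). Interferon response genes shifted by 0.42 (camera adjusted p = 1.21e-06, adjusted p = 0.376 with an estimated correlation). Clock genes shifted by a median of -0.46 (camera adjusted p = 0.0126, adjusted p = 0.376 with an estimated correlation), a call lost without TBT replicate 5 of 5 months (adjusted p = 0.103). Across 13055 genes, which are not independent replicates, the TBT effects at 5 and 10 months had Pearson's r of 0.129 and Spearman's rho of 0.064. In 18 of 100 labellings of the samples within each age, the real one included, r was as large in size, with either sign. The other labellings gave r from -0.227 to 0.276.

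At 10 months the changes of TBT liver and of adenoma against the same VEH livers were set side by side. Across 13474 genes r was 0.444, below the mean of 0.505 ± 0.014 (SD) in 20 simulations of unchanged groups that share the VEH libraries. Over the 9415 genes with a mean of at least 5 CPM r was 0.513, above the simulated mean of 0.498 ± 0.014. The covariance was 0.13 against a simulated mean of 0.0333, a difference of 0.0964, over all genes. With separate VEH libraries for each comparison, in 20 splits, the median covariance was 0.114 (0.0679 to 0.161) and the median r was 0.31 (0.193 to 0.415). The same sign held for 66.5% of genes, against 66.6% in the simulations, and edgeR called 0 genes in both comparisons because it called 0 in TBT liver (595 at an unadjusted p under 0.05 in this fit). The simulated adenomas were unchanged too, with genes drawn independently, whereas edgeR called 7090 genes in the real adenomas. The simulated r, covariance and share of same sign are therefore not a like reference, and no conclusion is drawn from them.

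**Figure D2:**
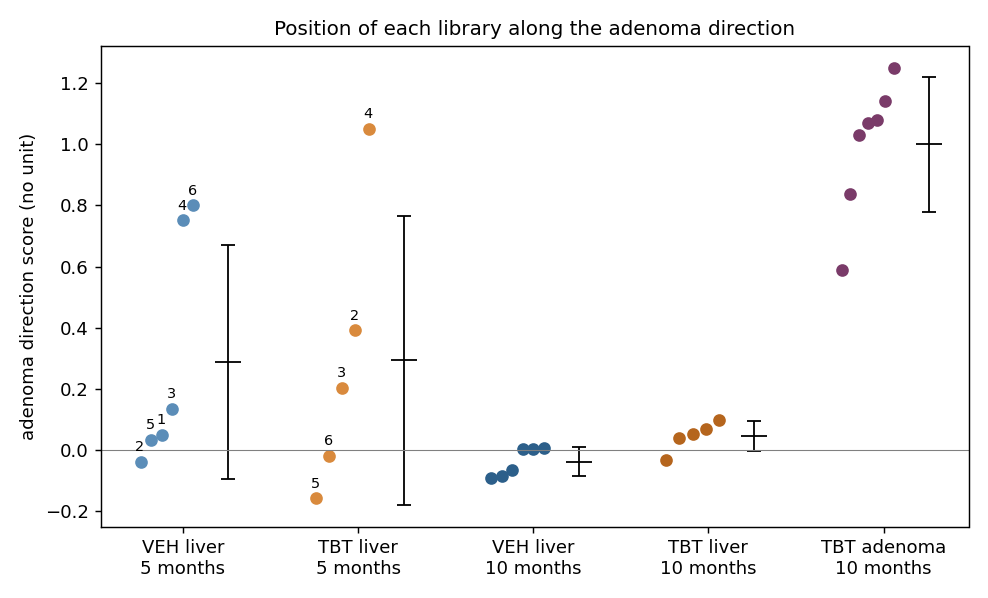
Score of each library along the adenoma direction, the projection of its log2 deviation from the mean of 10-month livers on the mean adenoma deviation (adenomas average 1), by group, with bars for mean and SD. Adenomas lie from 0.588 to 1.25, and 5-month VEH replicates 4 and 6 and TBT replicate 4 lie at 0.751, 0.8 and 1.05.

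**Figure D3:**
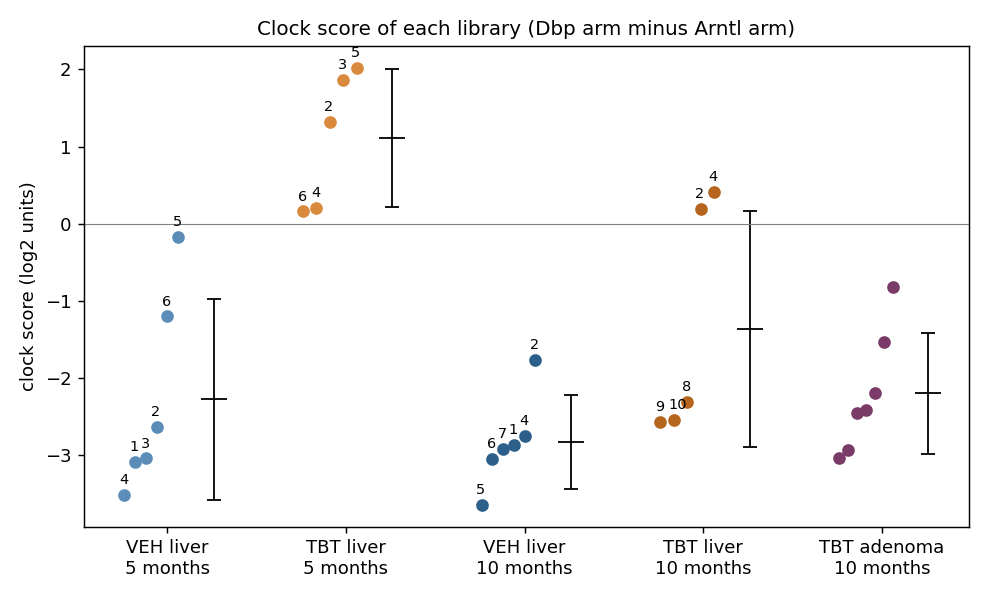
Clock score of each library, the mean log2 level of Dbp-arm genes minus that of Arntl-arm genes, by group, with bars for mean and SD. TBT libraries of 5 months lie from 0.16 to 2.02 and VEH libraries of 5 months from -3.51 to -0.17.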

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

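The tests of adenoma-like values and of the time of collection were chosen after the results they bear on were seen, as were the further comparisons for gallbladder and pancreas, and the other tests of this part were written before their results.

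VEH replicates 4 and 6 and TBT replicate 4 of 5 months resembled the adenomas of 10 months. Over all genes their deviation from the median of 5-month libraries correlated with the adenoma change at 0.69, 0.66 and 0.74, against -0.43 to 0.22 in the other 8, and Gpnmb was at 26.7 to 87.3 CPM against at most 1.43 CPM. The tables argue against shallow sequencing: with all libraries thinned to the smallest total these correlations were 0.63 to 0.76 against at most 0.21 in the other 8, a gap of 0.42, although 2 of the 3 libraries were among the 2 smallest totals of their group. Mislabelled 10-month adenomas stay open. The 3 libraries were scored at 34 genes chosen because the other 8 5-month libraries all lie beyond every 10-month library. The share on the 5-month side was 0.5 in TBT replicate 4, 0.529 in VEH replicate 4 and 0.618 in VEH replicate 6. The 10-month libraries (at most 0.0882) and the other 5-month libraries (at least 0.912) lie at the ends by that choice, so a share between them cannot decide. Adenoma tissue in these samples also stays open as an untested hypothesis, both arms held such libraries, and no test of an exposure effect on them was run.

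Clock genes parted TBT from VEH liver at 5 months in opposite directions by arm, with a median log2 fold change of 1.74 for the 11 genes of the Dbp arm and -1.68 for the 4 genes of the Arntl arm. The tables argue against shallow TBT libraries, as 8 clock genes were called with all libraries thinned to the smallest total. They also argue against the libraries with adenoma-like or intestinal values as the whole cause. For the 8 genes called with all libraries, the median size of the changes without these 4 was 0.972 times that with all. Still, 0 of the 8 passed in edgeR (all 8 unadjusted), with fewer libraries in the test. The 8 were chosen in a fit that included the remaining libraries. Collection at another time of day may give such a pattern, as the arms differed by 3.42, but the largest range within a group was 3.34 (VEH at 5 months), so this cannot be told apart from an effect of the exposure. At 10 months TBT replicates 2 and 4 scored 0.19 and 0.41 on the same scale, while replicates 8, 9 and 10 scored -2.31, -2.57 and -2.54.

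TBT replicate 2 of 5 months carried intestinal transcripts, with Reg1 at 200 and Clca1 at 122 CPM besides Sis and Alpi. Small intestine epithelium in the sample is a candidate source, as a hypothesis. Of 23 small intestine genes with at least 1 CPM in some 5-month library, 20 lay at over 5 times the highest of the other 10, a share of 0.87. Genes could enter that set through TBT replicate 2 itself, so a high share was partly fixed in advance. Without that filter, 1 of 24 listed small intestine genes was under 1 CPM in TBT replicate 2. Of the 23 genes, 4 were also expressed in 10-month liver. The tables argue against exocrine pancreas, with 16 of 19 listed genes under 1 CPM in this library, although only 5 entered the share, which was 0.2, or 0.6 without the 3 adenoma-like libraries and 0.4 against 10-month liver. Gallbladder stays open. Its share was 0.158, low enough to argue against it by the level set beforehand, but the libraries compared include the 3 adenoma-like ones. The share was 0.316 (6 of 19) without them and 0.368 (7 of 19) against 10-month liver. In this library 5 of its 20 listed genes were under 1 CPM. Of 7 gallbladder genes under 1 CPM in every 10-month liver, 1 lay at over 5 times the other 5-month libraries, against 19 of 19 for small intestine. That contrast also used the 3 adenoma-like libraries, and genes entered it only with at least 1 CPM in a 5-month library. It therefore cannot decide on gallbladder. No explanation by exposure or age was tested.

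Dixon's gap test, which sets the gap to the nearest value against the range, flagged single libraries in 15 of 103 groups of values. Its chance rate of 1 in 20 assumes normally distributed values, which CPM need not be. Some genes tested, such as Fcgbp and Lars2, had already been named for large changes, so the 15 cannot be read as an excess over chance. VEH replicate 5 of 5 months had a total of 33.7 M counts. At 5 months Fcgbp was at 634 CPM in TBT replicate 2 and 1.34 CPM in VEH replicate 4, and Slc5a1 at 457 CPM in TBT replicate 2 and 8.77 CPM in VEH replicate 6. Lars2 was at 26900 CPM in TBT replicate 4 and 195 CPM in VEH replicate 1 of that age. VEH replicate 3 of 5 months had 88.6 CPM of Cyp7a1 and 2.68 CPM of Cidec, and VEH replicate 1 had 12.9 CPM of Isg15. Adenoma 7 had 544 CPM of Mup7 and adenoma 6 had 1670 CPM of Glul. At 10 months TBT replicate 10 had 498 CPM of Slco1a1 and VEH replicate 7 had 33.4 CPM of Mt1. Krt20 was flagged at 0.0382 CPM in TBT replicate 4 of 10 months, with 0 CPM in the other TBT livers of that age. This level is too near the floor to set that library apart.

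Between 5 and 10 months the TBT effect differed for 7 lists under the preset correlation and 0 with an estimated correlation. The adjusted p was 2.45e-09 for acute phase, 7e-06 for erythroid, 0.0207 for stress response, 0.0126 for clock, 1.21e-06 for interferon response, 0.00803 for ribosomal protein and 1.94e-05 for nuclear oxidative phosphorylation genes. With an estimated correlation the adjusted p was 0.725, 0.376, 0.99, 0.376, 0.376, 0.99 and 0.99 in the same order.

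Splits of the samples into groups of the same sizes were drawn 100 times for each count, the real split included. No other split gave as many genes for adenoma against VEH liver (7090 genes, 1 of 100 as large, highest other 3961), adenoma against TBT liver (6026, 1 of 100, highest other 3821), age in VEH liver (2501, 1 of 100, highest other 96) and age in TBT liver (232, 1 of 100, highest other 7). Chance is thus unlikely for these counts, at the lowest share that 100 splits can give. The count for age in TBT liver still ranged from 14 to 801 when 1 library was left out. For TBT against VEH at 5 months, 13 of 100 splits gave at least 265 genes, so chance cannot be excluded. The highest other gave 1915 genes with VEH replicates 4 and 6 and TBT replicate 4 on the same side, which points to a structure of the samples. For TBT against VEH at 10 months and for the interaction, 100 of 100 splits gave at least 0 genes, with highest others of 1 and 441.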

How the results depend on the processing

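The omission of 5-month libraries with unusual values and the thinning of counts were chosen after the data were seen. Among named genes, 7421 values under other settings kept direction and side of the threshold, 760 lost the threshold, 26 gained it and 6 turned; among called lists 1332 kept both, 264 lost the call and 1 turned. Of named called genes, those called under every setting were 0 of 27 for TBT against VEH at 5 months, 96 of 110 and 96 of 103 for adenoma against VEH and against TBT liver, 27 of 64 for age in VEH and 0 of 29 for age in TBT liver. Shallow TBT libraries of 5 months limit the precision for low genes. Except where stated, the cause was not tested.

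At 5 months the 265 genes became 591 with DESeq2, 147 with limma-voom, 1 in a fit of the 2 groups compared, 153 with thinned counts and 47 without VEH replicates 4 and 6 and TBT replicates 2 and 4, where fewer samples were tested. Leaving out 1 library gave 71 to 414. For age in TBT liver the 232 genes became 843 with DESeq2, 35 with limma-voom, 401 in a fit of all 5 groups, 0 in a fit of the 2 groups compared (1881 unadjusted), 58 with thinned counts and 113 without the 4 libraries, and 14 to 801 without 1 library. The interaction gave 44 genes with DESeq2 and 0 to 1 without 1 library.

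Lists called with an estimated correlation numbered 0, 0, 0, 1, 0, 0 and 0 for TBT at 5 and 10 months, adenoma against VEH and against TBT, age in VEH and in TBT liver, and the interaction. Fry called 1 list for TBT at 5 months, 0 at 10 months, 3 for age in VEH, 1 for age in TBT liver and 0 for the interaction. Without VEH replicates 4 and 6 and TBT replicate 4 of 5 months, 7 lists were called for age in VEH liver and 12 for the interaction, and without TBT replicate 2 as well, 7 and 13. Leaving out 1 library gave 6 to 12 lists for TBT at 5 months, 7 to 18 for age in VEH liver and 5 to 13 for the interaction. The covariance of TBT liver and adenoma changes was 0.0685 over genes with a mean of at least 5 CPM. It was 0.0142 in simulations, which are not a like reference.

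Values that turned did so mostly without the 4 libraries: for age in TBT liver Fcgbp at 0.20, Smim24 at 0.30, Slc5a1 at 0.26 and the cell cycle list (adjusted p = 0.877). Gpnmb for age in VEH liver was 0.95 without the 3 adenoma-like libraries and 0.95 without the 4. Smim24 for age in TBT liver ranged from -5.66 to 0.05 when 1 library was left out.

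With the replicate block, on samples whose number occurs in both groups, 4 genes were called for TBT at 5 months (0 in those samples without it), 3860 for adenoma against VEH (4080 without), 1510 for age in VEH (2311 without) and 7 for age in TBT liver (0 without). At 5 months 3 of 5 same-numbered pairs correlated, at 0.42, 0.66 and 0.36, each TBT library best with its own number, and the others were at 0.03 and -0.46. Correlations were -0.14 to 0.16 in the other comparisons. Since not every pair was over 0.1, the numbers were not read as pairs. The block was not run for adenoma against TBT liver, whose numbers do not overlap.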

Other observations

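Lpl, Aqp7, Fabp4 and Cd36 were named after their values were seen, and no test of this part was chosen after its result was seen.

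Genes of lipid uptake and storage changed in adenomas in both directions. Cidec, which encodes a protein of lipid droplets, was at 72.3 ± 49.9 CPM in adenomas and 3.63 ± 1.39 CPM in VEH liver (SD, n = 7 and 6; log2 fold change 4.31, SE 0.52, edgeR adjusted p = 5.93e-06, above all VEH libraries in 7 of 7). Lpl, the lipase of circulating triglyceride, had a log2 fold change of 3.92 (SE 0.29), the glycerol channel gene Aqp7 7.11 (SE 0.77), the fatty acid carrier gene Fabp4 3.49 (SE 0.58) and the fatty acid transporter gene Cd36 1.96 (SE 0.46). G0s2, an inhibitor of triglyceride breakdown, was lower at -1.94 (SE 0.43). Of 20 lipid droplet and PPARG target genes 8 were higher and 4 lower, and 9 and 4 adjusted over the list alone. The list as a whole did not pass (median 0.67, camera adjusted p = 0.11), and Pparg itself had a log2 fold change of 0.61 (SE 0.28, adjusted p = 0.0762).

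Female-biased liver genes were higher in adenomas than in TBT liver, with 8 of 23 higher and 0 lower, and the same counts adjusted over the list alone (median 1.09, camera adjusted p = 0.0222, adjusted p = 0.52 with an estimated correlation). Cyp2a4, a steroid hydroxylase gene, was at 221 ± 230 against 3.11 ± 2.02 CPM (SD, n = 7 and 5; log2 fold change 6.17, SE 0.85, edgeR adjusted p = 3.62e-05, above all TBT livers in 7 of 7), and Cyp3a44 had 2.79 (SE 0.43). The list's call was lost without adenoma 6 or 7, with a highest adjusted p of 0.103. Against VEH liver 6 were higher and 1 lower (camera adjusted p = 0.0631). Translation and respiration genes were lower in adenomas than in VEH liver by small amounts, with 19 of 27 ribosomal protein genes lower (median -0.29, camera adjusted p = 2.41e-05) and 13 of 25 nuclear oxidative phosphorylation genes lower (median -0.18, camera adjusted p = 0.00396), each with adjusted p = 0.554 with an estimated correlation.

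TBT livers of 10 months may lie slightly toward the adenomas, as a hypothesis. Each library was scored along the mean difference of adenomas from all 10-month livers, a scale on which the adenomas average 1. TBT livers scored 0.0457 ± 0.0486 and VEH livers -0.0381 ± 0.0469 (SD, n = 5 and 6), a difference of 0.0839 with an exact two-sided permutation p of 0.0281 (13 of 462 relabellings), and 4 of 5 TBT livers lay above all VEH livers. The adenomas carry the TBT label too, so a shared effect of exposure and a shift toward tumour cannot be separated here, and no single gene passed between these livers (edgeR 0, 218 unadjusted; DESeq2 0; limma-voom 0).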
